A study of Mus musculus with 96 samples.

How the data were processed

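Gene expression was measured by mRNA sequencing of the striatum of mice that carried 1 knock-in Htt allele with a CAG repeat length label of 20, 50, 92 or 140, and of wild-type mice, at 6 and 10 months of age. The 96 libraries formed 12 groups of 8, each with 4 females and 4 males named as replicates 1 to 4 of their sex in the labels (F1 to F4 and M1 to M4 here). The wild types formed 2 cohorts by their housing label, 1 kept with Q20 mice and 1 kept with Q50 mice. Q92 and Q140 mice were kept only with their own genotype, so no wild types of their own cohort were labelled. Total RNA was extracted with a column kit and an enriched subfraction was sequenced by standard Illumina methods. CASAVA 1.8.2 is the only tool that the labels name; the aligner, the quantifier and the genome build are not given in the sources used here.

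The authors deposited 2 tables of 39179 Ensembl gene identifiers by 96 libraries. The deposited expected counts are estimated reads per gene with no normalization, and 27.7% of their non-zero values were fractional at a tolerance of 0.001. The deposited FPKM values are normalised by the authors for gene length and library total; the gene length that they imply against the counts had a median coefficient of variation between libraries of 0.83%. Every table column was matched to 1 label, with 0 columns left over. Symbols, gene types and distances to Htt came from the GENCODE M21 mouse annotation by identifier. A symbol was found for 37607 identifiers and none for 1572. Library totals ran from 29.1 to 40.2 M counts.

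Expected counts were rounded and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit) in R 4.3.3, with TMM normalization and the filterByExpr filter, and a Benjamini-Hochberg adjusted p under 0.05 over all genes tested was the threshold. All tests were two-sided. Each age was fitted alone with its 48 libraries in 6 groups plus sex, because the library numbers of the 2 ages form 2 separate runs. Q20 and Q50 were compared with the wild types of their own cohort. Q92 and Q140 were compared with the mean of both wild-type groups. The CAG length trend was the slope on CAG length over the 32 knock-in libraries of an age, printed for 120 units (from 20 to 140). The other fits compared the wild-type cohorts, the Q140 effect between sexes, the Q50, Q92 and Q140 effects between ages over 96 libraries, and sex and age over the 32 wild-type libraries. CPM stands for the usual scaling of counts to an equal library total, with TMM factors, and M for the prefix mega. In the text a value with ± is a mean and SD over 8 libraries, and a log2 fold change with ± has its standard error, with 8 knock-in libraries against 8 or 16 wild types.

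Comparisons, tests, the rule for named genes, 23 gene lists and all alternatives except 3 were chosen before the data were examined. The rule named Htt in every comparison. It also named, per comparison, the 8 largest rises and 8 largest falls among genes past the threshold with an average log2 CPM of at least 1 and the same direction in both sexes. From each fixed list it named the 2 members with the smallest p among those past the threshold. For effects by sex or age, for sex and for age it named 4 each way. The text prints a choice of the named genes and names others only where it says so.

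The fixed lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01 between genes, adjusted over the 23 lists. Camera with an estimated correlation and fry served as alternatives. Fry asks whether the genes of a list move on balance one way and does not compare a list with other genes. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. The lists covered shared striatal projection neuron, direct pathway, indirect pathway, striatal interneuron, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, blood vessel, cortical projection neuron and choroid plexus genes. They also covered cholesterol synthesis, activity-regulated, neurotransmitter receptor, ion channel, protein folding and stress, p53 target and apoptosis, mismatch repair, mitochondrial respiration, developmental transcription factor, clustered protocadherin, sex-chromosome genes and 14 genes beside Htt. Of 58 protocadherin symbols 24 were in the tables, and Tmem90a, Drd1a, Gpr52, Slc18a3, Tmem10, Lhfpl3, Sc5dl and Sc4mol were not found under these symbols. After the libraries were examined, 4 lists for other tissues were added: thalamus (10 genes), liver (8), midbrain dopamine neurons (7) and pituitary (4).

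Alternatives on counts changed 1 choice each, except that DESeq2 brought its own normalization and test, and limma on FPKM changed the values, the normalization, the filter and the test together. They were RLE normalization, no filter, a filter of CPM of at least 1 in 8 libraries, DESeq2 1.42.0, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM filter of 0.1 or none, the library code as a covariate, replicate number as a block, 1 sex alone, other controls, only the groups compared in the fit, other forms of the CAG trend, and each library left out in turn. The library code (L1 to L8, with the 2 libraries of other codes merged into 1 level) reached at most 3 libraries per group, so no value within a code was computed. The 3 alternatives added after the libraries were examined were the thalamus gene level as a covariate, thalamus and cortex levels as covariates, and the fit without 5 libraries with transcripts of another tissue, although other libraries with such transcripts were kept. Those 5 were Q50 10-month M4 (liver), Q20 10-month F4 and M4 and Q92 10-month F1 (thalamus) and Q50 6-month M3 (cortex).

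The tests were checked on simulated data with 50 genes changed at each of 4 sizes. For Q140 at 6 months edgeR called 74% of 1.25-fold changes, 90% of 1.5-fold, 98% of 2-fold and 100% of 4-fold changes, with 7 calls among 16992 unchanged genes. The smallest changes were called in 52% of cases for Q140 at 10 months, in 60% for Q20 at 6 months, in 22% for the Q140 effect by sex and in 46% for the Q140 effect by age. A simulated raised list was called by camera with either correlation, with 0 of 22 unchanged lists called, while fry called 3 of those 22. The simulated genes varied independently of each other at the fitted trend of spread, without tissue differences between libraries. Genes with few counts were not among those changed. Other splits of the real libraries gave up to 2576 calls (Q20 at 10 months), so the simulated shares need not hold in the real data.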

Results

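The striatum, the input nucleus of the basal ganglia and the brain region that degenerates first in Huntington's disease, was profiled by mRNA sequencing in an allelic series of Htt knock-in mice. Heterozygous mice with CAG length labels of 20, 50, 92 and 140 and wild types were sampled at 6 and 10 months, with 8 libraries in each of 12 groups. Library totals were 36.6 ± 1.59 M counts (SD, n = 48) at 6 months and 32.3 ± 1.51 M at 10 months, and ran from 29.1 to 40.2 M. Mitochondrial transcripts took 12% of counts at 6 months and 11.8% at 10 months. Genes typical of the thalamus, a neighbouring region, varied between libraries and groups. Their mean level over 10 genes ran from 1.81 ± 0.86 log2 CPM in Q50 mice at 6 months to 4.75 ± 1.03 in Q20 mice at 10 months. Across the 1000 most variable genes, the second principal component held 12% of the variance at 6 months and 12.8% at 10 months, with absolute correlations to that level of 0.82 and 0.87.

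**Figure D1:**
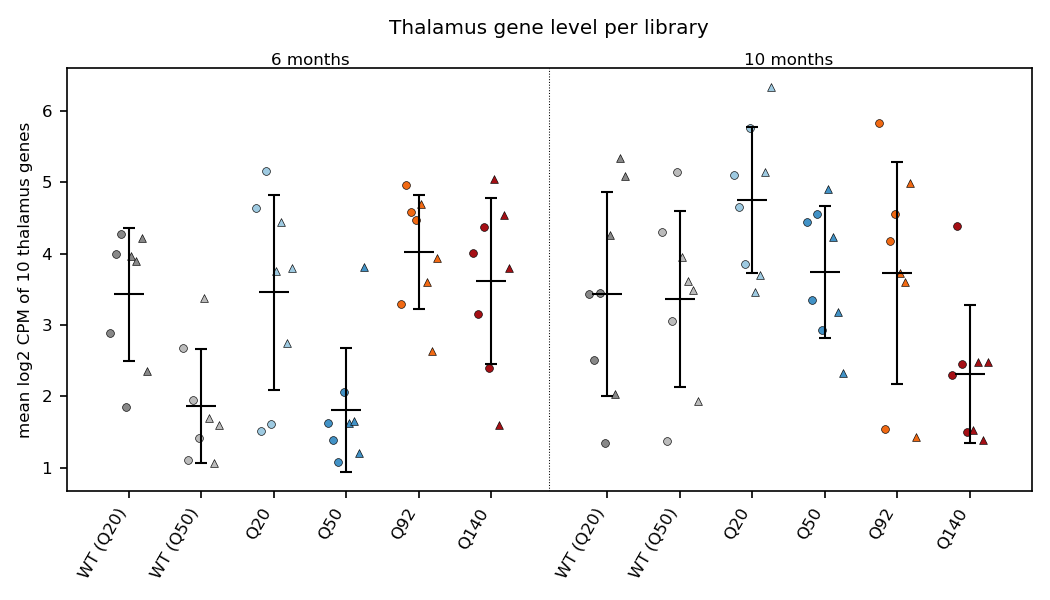
Mean log2 CPM of 10 thalamus genes in each library (circles females, triangles males) by group, with bars for the mean and SD of 8 libraries. At 6 months the Q92 mean was 4.02 and the wild-type means were 3.43 and 1.86; at 10 months the Q140 mean was 2.32 and the wild-type means were 3.43 and 3.36.

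Htt (ENSMUSG00000029104), the targeted gene on chromosome 5, was lower in Q140 mice at both ages. It stood at 173 ± 3.98 CPM in Q140 mice and at 191 ± 15.4 and 189 ± 18.4 in the wild types of the Q20 and Q50 cohorts at 6 months, and fell by 0.14 ± 0.041 on the log2 scale (adjusted p = 0.00726). All 8 Q140 libraries lay below the wild-type median and 0 lay below every wild type. At 10 months Htt stood at 165 ± 18.3 CPM in Q140 mice and at 204 ± 6.26 and 203 ± 11.6 in the wild types. It fell by 0.31 ± 0.042 (adjusted p = 4e-07), with 8 of 8 libraries below every wild type. In Q20, Q50 and Q92 mice Htt did not pass the threshold: the log2 fold changes were 0.096 ± 0.047, 0.090 ± 0.047 and 0.12 ± 0.040 at 6 months (smallest adjusted p = 0.0749) and 0.042 ± 0.048, 0.084 ± 0.048 and -0.037 ± 0.041 at 10 months. The counts of the 2 alleles were not separated in the deposited tables.

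Q140 mice against wild types at 6 months addressed the effect of the longest repeat at the younger age. All 29 measured genes shared by striatal projection neurons, the GABAergic neurons that form most of the striatum, fell, and all 29 also fell when adjusted over the list alone. Their median log2 fold change was -0.47 ± 0.041 (bootstrap SE over the 29 genes, not over mice). For this list camera gave an adjusted p = 2.17e-35, and adjusted p = 0.0322 with an estimated correlation. Arpp21, a cyclic AMP-regulated phosphoprotein, fell 1.82-fold, from 1385 ± 132 to 766 ± 92.0 CPM (adjusted p = 1.5e-14). Cnr1, the cannabinoid receptor CB1, fell 1.88-fold (adjusted p = 8.04e-13). Of 8 indirect pathway genes 4 fell (4 adjusted over the list alone; camera adjusted p = 1.01e-05, and adjusted p = 0.0322 with an estimated correlation). Penk, the enkephalin precursor, fell 2.09-fold, from 1167 ± 108 to 561 ± 72.8 CPM (log2 fold change -1.06 ± 0.062, adjusted p = 1.22e-17), and Gpr6, an orphan receptor, fell 1.68-fold. Of 9 direct pathway genes 5 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0426, and adjusted p = 0.543 with an estimated correlation). Drd1, the dopamine D1 receptor, fell 1.57-fold and Chrm4, the muscarinic M4 receptor, fell 1.45-fold. Each of these 6 genes was lower in 8 of 8 Q140 libraries than in every wild type.

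Ion channel and activity-regulated genes gave falls and clustered protocadherins gave rises in the same mice. Of 20 ion channel genes 11 fell (12 adjusted over the list alone; camera adjusted p = 4.16e-06, and adjusted p = 0.199 with an estimated correlation), among them Scn4b, a sodium channel beta subunit, 1.98-fold (adjusted p = 8.15e-13). Of 18 activity-regulated genes 7 fell (11 adjusted over the list alone; camera adjusted p = 0.000312, and adjusted p = 0.543 with an estimated correlation). Homer1, a postsynaptic scaffold protein, fell 1.90-fold and the transcription factor Egr2 fell 2.68-fold. Of 32 neurotransmitter receptor genes 8 fell and 3 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.067), with Gabrd, a GABA-A receptor subunit, 1.31-fold lower and Grm5, a metabotropic glutamate receptor, 1.26-fold lower. Clustered protocadherins, cell adhesion molecules of neurons, rose in 18 of 24 cases (19 adjusted over the list alone; camera adjusted p = 2.77e-12, and adjusted p = 0.038 with an estimated correlation). Pcdhb9 rose 1.37-fold and Pcdhb22 rose 1.46-fold; members of this family share near-identical sequence, so counts of single members are uncertain. Of 16 developmental transcription factor genes 6 rose and 1 fell, also over the list alone (camera adjusted p = 0.128). Wt1 rose from 0.0975 ± 0.0447 to 1.04 ± 0.478 CPM and Onecut1 from 0.121 ± 0.0611 to 0.92 ± 0.583 CPM.

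The other lists gave fewer or mixed calls at this age. Astrocyte genes gave 1 rise and 2 falls of 13, oligodendrocyte precursor genes 1 and 1 of 10, blood vessel genes 0 and 1 of 12, and oligodendrocyte, microglia and striatal interneuron genes 0 and 0. Cholesterol synthesis genes gave 0 rises and 3 falls of 17, protein folding and stress genes 0 and 3 of 17, p53 target and apoptosis genes 0 and 4 of 14, mismatch repair genes 2 and 0 of 14, and mitochondrial respiration genes 3 and 1 of 18. None of these lists passed camera (smallest adjusted p = 0.155). Adjusted over the list alone the falls were 0 for blood vessel genes, 5 for p53 target and apoptosis genes, and the rises 1 for mismatch repair and 2 for mitochondrial genes; the other counts were equal. Choroid plexus genes gave 1 fall of 10 (0 over the list alone) and cortical projection neuron genes 1 rise and 3 falls of 10, with a median of -0.88 (camera adjusted p = 0.183). Of 13 genes beside Htt 5 rose and 3 fell (5 and 4 adjusted over the list alone), with Adra2c, an alpha-2C adrenergic receptor, 1.37-fold lower. Sex-chromosome genes gave 0.

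In all, 4114 of 17339 genes passed the threshold, 2036 up and 2078 down, and 4194 passed without the 5 libraries set aside for other tissue. The largest falls by the rule were those of Gpx6 (4.45-fold), Phex (3.32-fold), Sec14l3 (3.20-fold), Abhd11os (2.87-fold) and Slc4a11 (2.82-fold), each below every wild type in 8 of 8 libraries, and those of Rn7s1, Slc30a3 and Neurod6. Slc30a3 and Neurod6 belong to the cortical projection neuron list. The level of that list was 1.58 ± 0.79 log2 CPM in Q140 mice against 2.36 ± 0.92 and 2.28 ± 0.88 in the wild types. The largest rises were those of Sfmbt2, a Polycomb-group gene (2.38-fold, adjusted p = 3.29e-15), Abhd1 (2.55-fold), Grid2ip, Fam205a2, Adamts19, Slc17a6, Mctp2 and Tcf7l2. Abhd1 changed as much in Q20 mice (log2 fold change 1.44, against 1.35 in Q140 mice). Grid2ip, Adamts19, Slc17a6 and Mctp2 were also among the largest Q92 rises at this age, which went with the thalamus level. Slc17a6, a vesicular glutamate transporter, and Tcf7l2 are thalamus genes, and Tcf7l2 had a log2 fold change of -0.038 against Q20 mice and -0.031 with thalamus and cortex covariates (0.96 against wild types); 4 of the 10 thalamus genes rose (9 adjusted over the list alone; camera adjusted p = 0.0229, and adjusted p = 0.911 with an estimated correlation), and their level was 3.62 ± 1.16 log2 CPM in Q140 mice against 3.43 ± 0.93 and 1.86 ± 0.80 in the wild types. Calls were lost without 1 library in 10 of 24 cases for Slc17a6, 13 for Tcf7l2, 12 for Neurod6 and 7 for Slc30a3; without wild-type Q20-cohort M4 for Rn7s1 (adjusted p = 0.169); without Q140 F3 for Fam205a2 (0.0501); and without Q140 M1 for Adamts19 (0.0507) and Mctp2 (0.0801). With limma on log2(FPKM + 1) the split was 3344 up and 1414 down, and against Q20 mice, in place of wild types, 2339 genes passed.

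**Figure D2:**
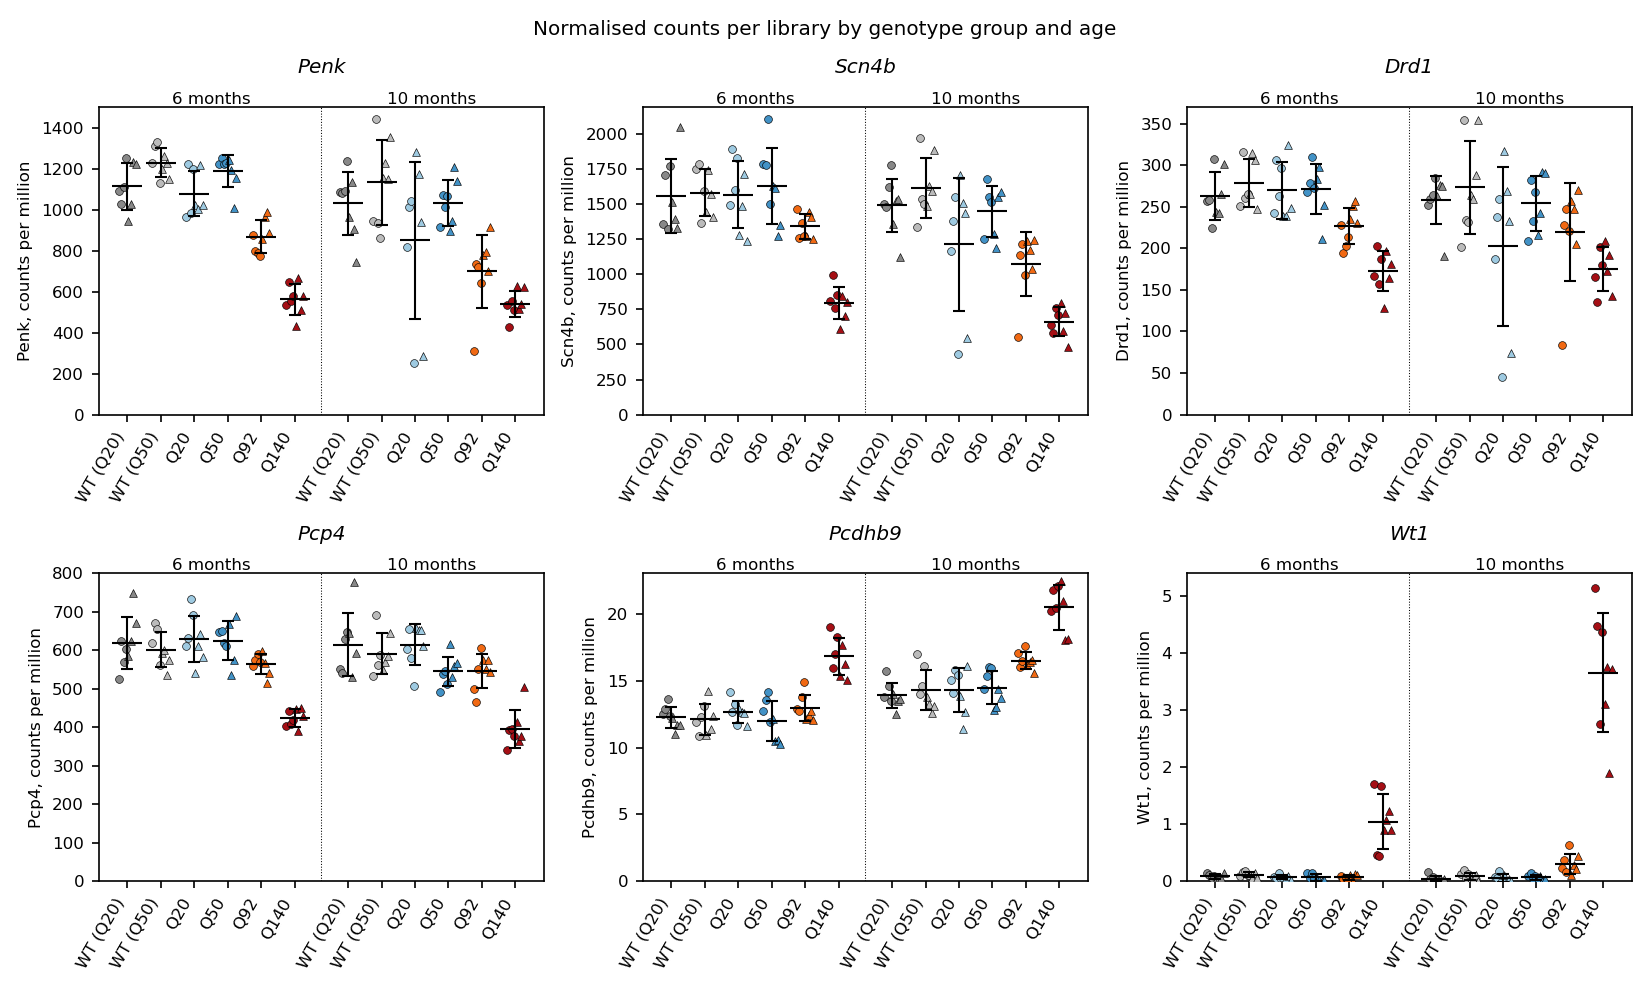
Normalised CPM of Penk, Scn4b, Drd1, Pcp4, Pcdhb9 and Wt1 in each library by group (circles females, triangles males), with bars for the mean and SD of 8 libraries. Penk averaged 561 CPM in Q140 mice and 1167 CPM in 16 wild types at 6 months, and 544 and 1090 CPM at 10 months.

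Q140 mice against wild types at 10 months repeated the comparison at the older age. Of 29 shared projection neuron genes 15 fell (18 adjusted over the list alone; median log2 fold change -0.49; camera adjusted p = 1.02e-10, and adjusted p = 0.395 with an estimated correlation). Pcp4, a calmodulin-binding peptide, fell 1.53-fold, from 606 ± 70.1 to 397 ± 49.6 CPM, and Rgs4, a regulator of G protein signalling, fell 1.66-fold. Of 8 indirect pathway genes 5 fell (6 adjusted over the list alone; camera adjusted p = 0.00462, and adjusted p = 0.194 with an estimated correlation), with Penk 2.01-fold lower (log2 fold change -1.01 ± 0.18, adjusted p = 7.03e-05) and Adora2a, an adenosine receptor, 1.65-fold lower. Direct pathway genes gave 3 falls and 2 rises of 9, also over the list alone (camera adjusted p = 0.995); their median was 0.052 although camera's direction was down. Scn4b fell 2.35-fold, from 1565 ± 209 to 666 ± 105 CPM, among 6 falls and 1 rise of 20 ion channel genes (8 and 1 adjusted over the list alone; camera adjusted p = 0.00146, and adjusted p = 0.53 with an estimated correlation). Of 32 receptor genes 9 fell and 2 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.29 with an estimated correlation). Htr2c, a serotonin receptor, rose 1.56-fold, from 70.2 ± 10.1 to 110 ± 5.97 CPM, and Gabrd fell 1.45-fold. Protocadherins rose in 17 of 24 cases and fell in 1 (19 and 1 adjusted over the list alone; camera adjusted p = 6.22e-15, and adjusted p = 0.0456 with an estimated correlation), with Pcdhb3 1.72-fold and Pcdhb9 1.45-fold higher.

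Some astrocyte and vessel genes fell at this age, though neither list passed with an estimated correlation. Of 13 astrocyte genes 6 fell (9 adjusted over the list alone; camera adjusted p = 0.000952, and adjusted p = 0.161 with an estimated correlation), with Glul, glutamine synthetase, at 1264 ± 77.2 against 1507 ± 131 CPM and Gja1, the gap junction protein connexin 43, 1.14-fold lower. The astrocyte median was -0.14, and between the 2 wild-type cohorts it was -0.095 at this age. Of 12 blood vessel genes 4 fell (7 adjusted over the list alone; camera adjusted p = 0.000164, and adjusted p = 0.109 with an estimated correlation), with Pecam1 1.17-fold lower. Of 12 oligodendrocyte genes 5 fell, also over the list alone (camera adjusted p = 0.151), among them the myelin gene Mal, but with the thalamus level as a covariate 3 oligodendrocyte genes rose and 2 fell. Microglia and striatal interneuron genes gave 0 calls. Cholesterol synthesis genes gave 4 falls of 17 (4 over the list alone), led by Msmo1, a sterol oxidase (1.23-fold), and activity-regulated genes 3 of 18 (3), with Homer1 1.69-fold lower. Mismatch repair genes gave 3 rises of 14 (5 rises and 1 fall over the list alone), among them Mlh3 (1.09-fold). Atf3, a stress-induced transcription factor, rose 2.11-fold among 2 rises and 1 fall of 17 protein folding and stress genes. Wt1 rose from 0.0631 ± 0.0595 to 3.67 ± 1.05 CPM and Onecut1 from 0.116 ± 0.078 to 2.82 ± 0.841 CPM, among 3 rises and 1 fall of 17 developmental transcription factor genes (3 and 3 over the list alone; median -0.10, camera direction up, adjusted p = 0.345).

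At 10 months 3324 of 17285 genes passed the threshold, 1863 up and 1461 down, and 4482 passed without the 5 libraries set aside for other tissue. The largest rises were those of Dsp, a desmosome protein (3.94-fold), Sfmbt2 (3.03-fold), Abhd1 (2.67-fold), Kazald1, Emx2os, Tnnt2, Slc45a3 and Dsg2, a desmosomal cadherin (1.95-fold). The largest falls were those of Gpx6 (6.72-fold), Sec14l3 (4.47-fold), Abhd11os (3.70-fold), Ryr1, an intracellular calcium channel (3.45-fold, from 111 ± 20.5 to 32.2 ± 6.17 CPM), Vwa7, Phex, Slc4a11 and Ddit4l, an inhibitor of mTOR signalling (3.22-fold). The thalamus level was 2.32 ± 0.96 log2 CPM in Q140 mice against 3.43 ± 1.43 and 3.36 ± 1.23 in the wild types, and 0 of 10 thalamus genes passed (8 falls adjusted over the list alone; camera adjusted p = 0.0098, and adjusted p = 0.924 with an estimated correlation). Mlh3 was not past the threshold in 7 of 24 fits without 1 library. Females alone gave 862 genes, males alone 1182, and limma on log2(FPKM + 1) gave 3069 up and 984 down.

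**Figure D3:**
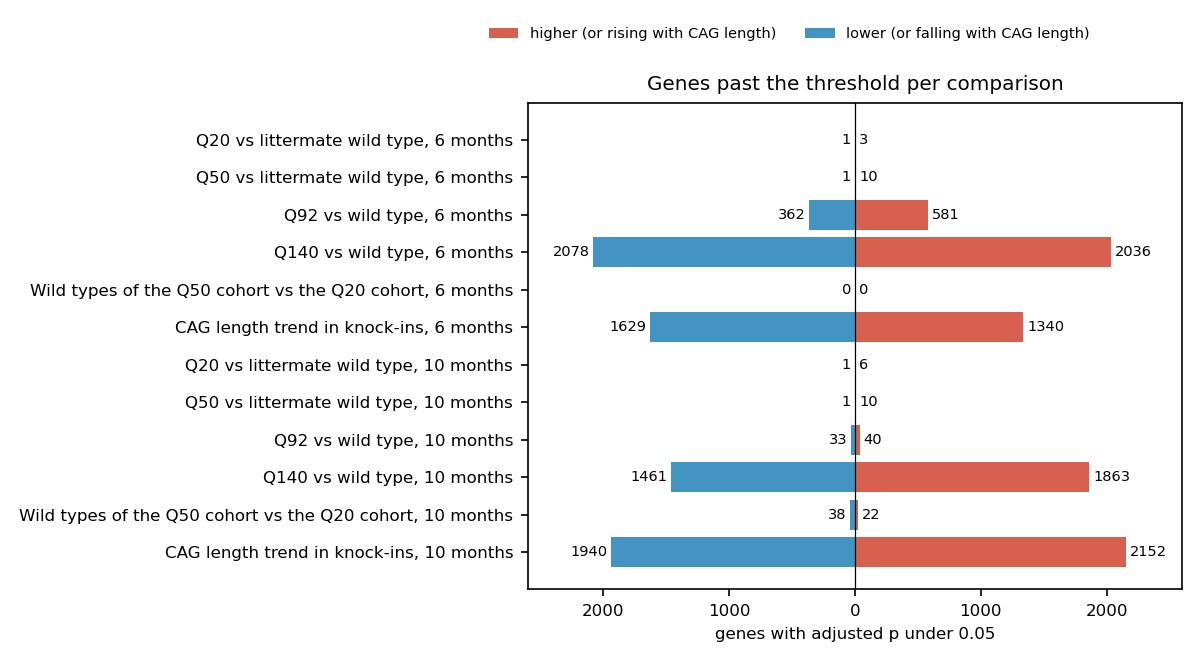
Numbers of genes past an adjusted p of 0.05 that rose and fell in 12 comparisons by edgeR, as bars from 0. Q140 gave 4114 genes at 6 months and 3324 at 10 months, Q92 gave 943 and 73, and Q20 and Q50 gave between 4 and 11.

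Q92 mice against wild types at 6 months showed smaller changes of several Q140 genes. Penk fell 1.35-fold, from 1167 ± 108 to 866 ± 78.9 CPM (log2 fold change -0.43 ± 0.060, adjusted p = 1.16e-05), Gpr6 1.28-fold and Arpp21 1.27-fold, and Ppp1r1b, the dopamine- and cyclic AMP-regulated phosphoprotein DARPP-32, fell 1.22-fold; each was below the wild-type median in 8 of 8 libraries. Of 29 shared projection neuron genes 7 fell (14 adjusted over the list alone; camera adjusted p = 2.85e-11, and adjusted p = 0.766 with an estimated correlation). The median of these genes was -0.15 and went to -0.026 with the thalamus level as a covariate, under which 1 fell. In males, with fewer libraries, 0 passed at a median of -0.13, and between the wild-type cohorts the median was 0.11. Indirect pathway genes gave 4 falls and 1 rise of 8 (4 and 2 over the list alone), direct pathway genes 2 falls of 9 (3 over the list alone), and protocadherins 2 rises of 24 (3 over the list alone); for the latter pair camera gave adjusted p = 0.0233 and 0.0204, and adjusted p = 0.766 for both with an estimated correlation. Krt9, a keratin, fell 1.49-fold, below every wild type in 8 of 8 libraries (adjusted p = 1.3e-06), and Homer1 fell 1.37-fold. Gabrb2, a GABA-A receptor subunit, rose 1.36-fold among 4 rises and 1 fall of 32 receptor genes (4 and 2 over the list alone). The other large falls were those of Shisa2, Dusp14, ENSMUSG00000079488, Alas2 and Hbb-bt, both active in red blood cells, Gpx6 and Gm15721.

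The largest Q92 rises at 6 months went with the thalamus level. They were those of Grid2ip (3.60-fold), Prkcd (3.44-fold), Slc17a6 (2.99-fold), Vipr2, Adamts19, Tnnt1, Mctp2 and Ptpn3, with SDs between libraries of up to 88.2 CPM around a mean of 172 for Prkcd. Of 10 thalamus genes 6 rose (9 adjusted over the list alone; camera adjusted p = 1.89e-07, and adjusted p = 0.254 with an estimated correlation), at 4.02 ± 0.80 log2 CPM against 3.43 ± 0.93 and 1.86 ± 0.80 in the wild types, and the median of cortical projection neuron genes was -0.84 with 0 of 10 past the threshold. In total 943 genes passed, 581 up and 362 down, and 1004 without the 5 libraries set aside for other tissue. The count was 48 with the thalamus level as a covariate, 17 against the Q20-cohort wild types alone, 1870 against the Q50-cohort wild types alone, 520 in females and 10 in males, and fell to 214, 290, 399 and 409 without Q92 F2, F3, F4 and M1 and to 601 without wild-type Q20-cohort F4. The calls of Slc17a6 and Tnnt1 were lost in 16 and 17 of 24 fits without 1 library, those of Prkcd in 6, ENSMUSG00000079488 in 7, Ptpn3 and Shisa2 in 5, Vipr2 and Adamts19 in 4, those of Dusp14 and Gpx6 without Q92 F2 or F3, and those of Alas2 and Hbb-bt without Q92 F2 (adjusted p = 0.0536 and 0.0576).

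Q92 mice against wild types at 10 months gave 73 genes, 40 up and 33 down. Krt9 fell 1.93-fold, from 32.3 ± 5.61 to 16.8 ± 3.83 CPM (adjusted p = 0.00208), Sec14l3 1.86-fold, Plk5 1.75-fold, Ddit4l 1.68-fold and Rgs4 1.31-fold, and Gm15721, Otof, Serpinb1b and Gm26673 fell too. Lrrn3, a neuronal leucine-rich repeat protein, rose 1.26-fold, Abhd1 2.25-fold, Htr2c by a log2 change of 0.32 and Wt1 4.86-fold, from 0.0631 ± 0.0595 to 0.305 ± 0.176 CPM. Of 29 shared projection neuron genes 1 fell (4 adjusted over the list alone; camera adjusted p = 2.26e-12, and adjusted p = 0.582 with an estimated correlation). Without the 5 libraries 6 fell, while their median went from -0.25 to -0.14. Of 24 protocadherins 1, Pcdhb9, rose (5 over the list alone; camera adjusted p = 2.9e-06, and adjusted p = 0.504 with an estimated correlation). Camera also passed indirect pathway, oligodendrocyte, cholesterol synthesis and ion channel genes as lower and mitochondrial genes as higher, 7 of 23 lists in all. Of the 7, 0 passed with an estimated correlation (adjusted p = 0.504 at the lowest). Gh, growth hormone, stood at 6.16 ± 9.24 CPM in Q92 mice and 0.0473 ± 0.0731 in wild types. Of 3 tested pituitary genes 2 rose (3 over the list alone, camera adjusted p = 3.74e-06, and adjusted p = 0.0109 with an estimated correlation). The pituitary level was 3.29 log2 CPM in Q92 F4, 2.03 in M2 and 1.34 in F3, and between -3.23 and -0.24 in the other Q92 libraries. It reached 3.47 in wild-type Q50-cohort 6-month F2, so such levels also arose without a knock-in allele. The thalamus level was 3.73 ± 1.56 log2 CPM, against 3.43 ± 1.43 and 3.36 ± 1.23 in the wild types. Without the 5 libraries 206 genes passed, with only the groups compared in the fit 147 (47 up and 100 down), with the thalamus level as a covariate 129, in females 40, in males 0, against Q20 mice 295 and without Q92 F4 41. Rises of Dsg1c, Htr2c, Adamts6, Tmem150a and Stard5 and the fall of Otof were lost in 4, 9, 5, 12, 12 and 5 of 24 fits without 1 library, and the fall of Gm26673 without Q92 F4, M1 or M3.

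Q20 and Q50 mice against the wild types of their own cohort showed few changed genes, most of them on chromosome 5 near Htt. Abhd1, 3.81 Mb from Htt, rose 2.70-fold in Q20 mice (from 1.86 ± 0.36 to 5.03 ± 0.322 CPM, adjusted p = 3.44e-09) and 2.26-fold in Q50 mice at 6 months, and 2.25-fold and 2.46-fold at 10 months. Dpysl5, 4.05 Mb away, rose by between 1.21-fold and 1.34-fold and Atraid, 3.71 Mb away, fell by between 1.15-fold and 1.27-fold in the same 4 comparisons. Gm2420, 2.04 Mb from Htt and chosen after its values were seen, also passed in all 4. In Q50 mice alone the more distant Galnt11 (9.54 Mb; 1.21-fold and 1.20-fold) and, chosen after their values were seen, Gm5067, Gm10471, 5031410I06Rik and 6030443J06Rik (8.66 to 12.21 Mb) passed at both ages. Galnt11 had a log2 fold change of -0.037 ± 0.057 in Q20 mice at 6 months. Counts were 4 for Q20 and 11 for Q50 at 6 months and 7 and 11 at 10 months, of which 4, 9, 4 and 9 lay within 20 Mb of Htt, where 1.52% of tested genes lie.

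No member of a fixed list passed in Q20 or Q50 mice, and the calls outside chromosome 5 were few. They were Gm11331 and the long non-coding RNA gene Gm6410, which passed in Q50 mice at both ages, and Grin2c, an NMDA receptor subunit (1.21-fold), Gm49342 and Slc6a3, the dopamine transporter, in Q20 mice at 10 months; Gm11331, Gm6410 and Slc6a3 were chosen after their values were seen. Slc6a3 was the 1 of 4 tested midbrain dopamine neuron genes to rise (4 over the list alone; camera adjusted p = 0.00177, and adjusted p = 0.0936 with an estimated correlation). Library F4 stood apart from the other 7 with Slc6a3 at 57.9 CPM and a midbrain level of 2.8 log2 CPM (others -0.53 to 0.69). Midbrain genes also passed camera in Q20 mice at 6 months (adjusted p = 0.0434, and adjusted p = 0.164 with an estimated correlation), where library F1 stood apart. The Q20 thalamus level at 10 months was 4.75 ± 1.03 log2 CPM against 3.43 ± 1.43 in its wild types, with 0 of 10 genes past the threshold. Camera passed thalamus genes there (1.39e-05, and adjusted p = 0.157 with an estimated correlation) and in Q50 mice at 10 months (0.0378, and adjusted p = 0.606 with an estimated correlation). Pituitary genes gave 0 past the threshold in Q20 mice at 10 months (3 rises over the list alone; camera adjusted p = 0.00154, and adjusted p = 0.0936 with an estimated correlation). Library F2 stood apart in these genes at 4.79 log2 CPM (others -3.23 to -0.02). Camera also passed pituitary genes in Q20 mice at 6 months (adjusted p = 0.00438, and adjusted p = 0.164 with an estimated correlation). It passed them in Q50 mice at 6 months (0.0313, and adjusted p = 0.42 with an estimated correlation) and at 10 months (0.0328, and adjusted p = 0.372 with an estimated correlation). Liver genes passed in Q50 mice at 10 months (5 of 5 rises over the list alone, adjusted p = 0.0345, and adjusted p = 0.5 with an estimated correlation), where library M4 stood apart. Shared projection neuron genes had a median log2 fold change of -0.29 in Q20 mice at 10 months with 0 of 29 past the threshold, and 0 over the list alone (camera adjusted p = 1.71e-10, and adjusted p = 0.378 with an estimated correlation). Libraries F4 and M4, both rich in thalamus genes, stood apart in this group, with Penk at 254 and 288 CPM against 819 to 1283 CPM in the other 6. Camera passed 11 of 23 lists in Q20 mice at 10 months. Besides this list, direct pathway, neurotransmitter receptor, ion channel and protocadherin genes were lower. Higher were astrocyte, oligodendrocyte, blood vessel, choroid plexus, protein folding and mitochondrial genes. For these 11 lists the adjusted p with an estimated correlation was 0.688 for oligodendrocyte genes and 0.378 for the others. Of the 23 lists camera passed 3 in Q20 mice at 6 months, and 1 and 3 in Q50 mice at 6 and 10 months. With an estimated correlation 0 passed in each. Without the 5 libraries the gene counts were 4 (Q20) and 11 (Q50) at 6 months and 5 and 11 at 10 months. For Q20 at 10 months 3267 genes passed with the library code as a covariate and 767 against both wild-type groups, and between 3 and 11 without 1 library: 3 without wild-type F2, F3 or F4, 4 without Q20 F4 or wild-type F1, M2 or M3, and 11 without wild-type M4. For Q50 at 10 months 20, 18, 22, 19, 21, 20 and 20 genes passed without Q50 F1, F2, F3, F4, M1, M2 and M3 and 17 without wild-type F3. Fits without 1 library lost Galnt11 in 9 and Atraid in 11 of 16 cases at 6 months, and Grin2c in 13, Gm49342 in 10 and Dpysl5 in 6 of 16 cases in Q20 mice at 10 months.

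**Figure D4:**
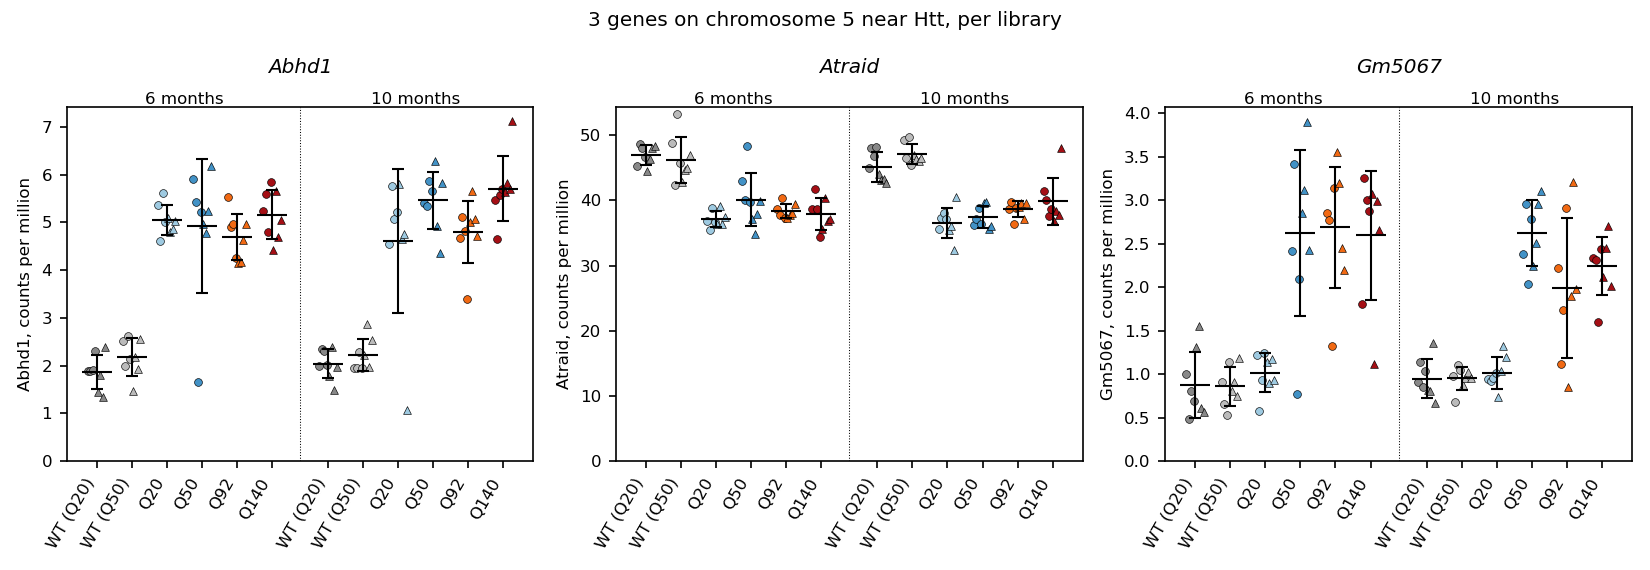
Normalised CPM of Abhd1, Atraid and Gm5067 in each library by group (circles females, triangles males), with bars for the mean and SD of 8 libraries. Abhd1 ran from 1.34 to 2.87 CPM in 32 wild types and lay above that range in 62 of 64 knock-in libraries.

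The CAG length trend over the knock-in mice asked which genes changed with repeat length without use of wild types. Each length was 1 cohort by its housing label, so length and cohort cannot be told apart. At 6 months all 29 shared projection neuron genes fell with length, also over the list alone (camera adjusted p = 1.84e-29, and adjusted p = 0.11 with an estimated correlation), and Penk fell by 1.03, Arpp21 by 0.87 and Pcp4 by 0.58 on the log2 scale over 120 units. Of 18 activity-regulated genes 10 fell (13 over the list alone; camera adjusted p = 5.03e-07, and adjusted p = 0.216 with an estimated correlation), of 20 ion channel genes 10 (11; 1.31e-05, and adjusted p = 0.216 with an estimated correlation), and of 24 protocadherins 18 rose (21; 4.01e-13, and adjusted p = 0.11 with an estimated correlation). Choroid plexus genes fell in 6 of 10 cases (7 over the list alone; camera adjusted p = 0.00264, and adjusted p = 0.548 with an estimated correlation). All 3 tested pituitary genes fell, also over the list alone (camera adjusted p = 0.0579). Sfmbt2 rose by 1.33 and Wt1 by 4.86 on the log2 scale, while Gpx6 fell by 2.19, Sec14l3 by 1.61, Phex by 1.58, Shisa2 by 1.59 and Plk5 by 1.43. Htt fell by 0.22 (adjusted p = 0.000638). The count was 2969 of 17120 genes, 1340 up and 1629 down, 3095 without the 5 libraries, 0 over Q20, Q50 and Q92 alone, and 2381 up and 1081 down with limma on log2(FPKM + 1). Ttr, a choroid plexus gene that fell by 1.62, was lost in 23 of 32 fits without 1 library and Xlr3b, which rose by 0.97, in 4.

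At 10 months 4092 of 17044 genes had a slope on CAG length past the threshold, 2152 up and 1940 down. Protocadherins rose in 18 of 24 cases (19 over the list alone; camera adjusted p = 2.52e-15, and adjusted p = 0.0814 with an estimated correlation), Wt1 rose by 7.14 and Onecut1 by 4.13 on the log2 scale over 120 units, Dsp by 1.77 and Htr2c by 0.67. Mismatch repair genes gave 5 rises of 14 (6 over the list alone; camera adjusted p = 0.0806), with Mlh3 up by 0.26 and Msh3 by 0.25. Of 29 shared projection neuron genes 6 fell, also over the list alone (camera adjusted p = 0.0806), with Pcp4 lower by a log2 change of -0.57 and Rgs4 by -0.59, and of 9 interneuron genes Pvalb and Calb2 fell. Astrocyte genes fell in 8 of 13 cases (8 over the list alone; camera adjusted p = 9.15e-06, and adjusted p = 0.108 with an estimated correlation) and vessel genes in 6 of 12 (6; 0.0011, and adjusted p = 0.205 with an estimated correlation). Htt fell by 0.36 (adjusted p = 3.42e-05). All 10 thalamus genes fell with length, also over the list alone (camera adjusted p = 1.63e-07, and adjusted p = 0.266 with an estimated correlation), and the named falls of Slc17a6, Lhx9, Abhd12b, Tnnt1, Prkcd, Slc6a3 and Pmch stood beside them. With the thalamus level as a covariate 2360 genes passed, and the slopes of Abhd12b, Tnnt1, Prkcd, Rorb and Ppargc1a turned positive; over Q20, Q50 and Q92 alone 39 genes passed, in females 454 and without the 5 libraries 4266. The call of Pmch was lost without Q20 F4 (adjusted p = 0.333), that of Tnnt1 without Q20 M4 (0.0667), that of Abhd12b without Q140 M1 or either of those 2, that of Tbr1 without Q140 F4 or M3, and that of Ppargc1a in 7 of 32 fits.

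The 2 wild-type cohorts differed by 0 genes at 6 months with edgeR (2574 genes at an unadjusted p under 0.05, 179 genes with DESeq2) and by 60 at 10 months. At 10 months Zbtb16, a transcription factor, was 3.53-fold lower in the Q50 cohort (8.11 ± 1.88 against 28.4 ± 14.1 CPM, adjusted p = 4.16e-05), Plin4, a lipid droplet protein, 3.38-fold and Hif3a 2.35-fold lower. Wnt7a, a secreted signalling protein, was 1.36-fold and Clec14a, an endothelial gene, 1.55-fold higher. Glul was the 1 of 13 astrocyte genes that fell (2 over the list alone; camera adjusted p = 0.00782, and adjusted p = 0.673 with an estimated correlation). At 6 months 9 of 23 lists passed camera between the wild-type cohorts, more than for Q140 (6) or Q92 (4) at that age. Of the 9, 0 passed with an estimated correlation, so camera calls with the preset correlation also arise without a genotype difference. Of these lists, 8 of 13 microglia genes were higher and 10 of 18 mitochondrial genes lower when adjusted over the list alone (camera adjusted p = 2.32e-07 for both, and adjusted p = 0.142 and 0.212 with an estimated correlation), and the thalamus level was 1.86 ± 0.80 against 3.43 ± 0.93 log2 CPM. Without 1 library the 6-month count was 114 (Q20-cohort F4), 60 (Q20-cohort M4), 22 (Q50-cohort F4), 5 (Q50-cohort M2) and 4 (Q50-cohort M4), and the 10-month count 24 (Q20-cohort F2), 37 (Q20-cohort F4), 31 (Q20-cohort M4), 32 (Q50-cohort F3 and M1) and 37 (Q50-cohort M2). Without the 5 libraries, none of them wild type, the shared fits gave 7 and 138 genes.

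No difference of the Q140 effect between females and males passed the threshold with edgeR, which gave 0 genes at both ages, with 353 and 763 genes at an unadjusted p under 0.05 and 1 gene at each age with DESeq2. The smallest adjusted p was 0.3 at 6 months and 0.955 at 10 months. Htt had a female minus male difference of effects of 0.011 ± 0.081 at 6 months and 0.075 ± 0.085 at 10 months (log2). Without Q140 F2 at 6 months 1 gene passed.

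Effects that differed between ages were tested against the same controls. The Q140 effect differed for 215 genes, 117 up and 98 down from 6 to 10 months: Wt1 by 2.48 ± 0.45 (log2; adjusted p = 0.00252), Emx2os by 1.02 ± 0.17 and its neighbour Emx2, a developmental transcription factor, by 0.68 ± 0.16, while Pecam1, a vessel gene, differed by -0.25 ± 0.068. Thalamus genes gave 3 falls of 10 (9 over the list alone; camera adjusted p = 3.13e-09, and adjusted p = 0.144 with an estimated correlation), among them the named Slc17a6 and Lhx9. The Q92 effect differed for 12 genes, 11 up and 1 down, among them Wt1 (2.81 ± 0.57), Dsg1c (0.95 ± 0.19), Lrrn3 (0.40 ± 0.077) and E2f5 (0.37 ± 0.071). The Q50 effect differed for 16 genes, all up, among them Alb, albumin; all 7 tested liver genes passed (7 over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.5 with an estimated correlation). The Q50 count was 0 without Q50 10-month M4 or without wild-type Q50-cohort 6-month F3, and 0 without the 5 libraries, which gave 70 for Q92 and 861 for Q140. The Q140 count was 8 with the library code as a covariate, 27 against the Q20-cohort wild types, 48 without a filter, 57 with thalamus and cortex covariates and 1607 against Q20 mice. Of the named Q140 genes Emx2os and Wt1 kept their calls in all 48 fits without 1 library. Emx2 lost it in 6, Pecam1 in 17, Lhx9 in 18 and Slc17a6 in 29 of them, and the total ran from 5 to 589. The balance of rises and falls turned between these fits. It was 219 up and 370 down without Q140 10-month F2, and 235 up and 212 down without Q20-cohort wild-type 6-month M1.

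In wild types 52 of 16581 genes differed between females and males, 39 higher and 13 lower in females. Xist, which silences 1 X chromosome, stood at 1543 ± 158 CPM in 16 females and 0.746 ± 0.356 in 16 males, and Eif2s3y, Ddx3y, Kdm5d and Uty of the Y chromosome at between 20.3 and 80.2 CPM in males and at most 0.0126 CPM in females. Of 8 sex-chromosome genes 4 rose and 4 fell, also over the list alone (camera adjusted p = 1.62e-08, and adjusted p = 1.52e-05 with an estimated correlation). Outside the sex chromosomes H2-Q7, H2-Q6 and Fmo2 were 1.78-fold, 1.70-fold and 1.55-fold higher in females. H2-Q6 lost its call in 22 of 32 fits without 1 library.

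Between 6 and 10 months 1615 of 16581 genes differed in wild types, 687 up and 928 down at 10 months, but the library numbers of the 2 ages form separate runs, so age and sequencing set cannot be told apart. With the library code as a covariate 18 genes passed. Egr4, an immediate early gene, was 1.76-fold and Junb 1.58-fold lower among 3 falls of 18 activity-regulated genes (5 over the list alone; camera adjusted p = 0.00141, and adjusted p = 0.855 with an estimated correlation), and Nrgn, a postsynaptic calmodulin-binding protein, was 1.28-fold lower. Protocadherins gave 4 rises of 24 (5 over the list alone), with Pcdhb9 1.16-fold higher, and the largest named rises were those of the pseudogenes Rpl17-ps8, Vcp-rs and Gm5537 and of ENSMUSG00000083840. The thalamus genes gave 0 of 10 past the threshold (7 rises over the list alone; camera adjusted p = 0.00705, and adjusted p = 0.32 with an estimated correlation). Junb lost its call in 17 of 32 fits without 1 library.

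Q92 and Q140 were compared with the same wild types, which by itself makes their fold changes correlate. Across 17339 genes, which are not independent replicates, the log2 fold changes of Q92 and Q140 at 6 months had Pearson's r = 0.656 and Spearman's rho = 0.614; 20 simulated pairs of unchanged groups against the same controls averaged r = 0.45, with a highest r of 0.483. The covariance was 0.0348 against a simulated 0.0102, a difference of 0.0246. With controls split by cohort r was 0.399 and 0.381. Both comparisons called 358 genes up and 290 down, against 68.2 and 43.4 for independent calls, which do not allow for the shared controls. The simulated groups held no tissue difference, while the thalamus level was 4.02 log2 CPM in Q92 and 3.62 in Q140 mice. It was 3.43 and 1.86 in the wild types of the Q20 and Q50 cohorts. How much of the likeness came from tissue in the dissections was not tested. At 10 months r was 0.378, below the simulated 0.438; the covariance was 0.0194 against 0.0123, a difference of 0.0071, the split controls gave r = 0.19 and 0.15, and 32 genes rose and 31 fell in both against 4.3 and 2.8. Between ages r was 0.383 for Q140, with 770 genes up and 758 down at both ages against 220 and 176.1 for independent calls and 13 in opposite directions, and 0.102 for Q92, with 10 up and 7 down against 1.4 and 0.7.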

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

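Chosen only after the result was seen were the tests of a change of the Q92 effect with age, of a chromosome 5 segment, of segment ends and of the Q20 and Q50 changes near Htt against those of Q140, the thalamus and cortex covariates, the fit without 5 libraries, the 4 tissue lists, and the rule on glial and vessel lists for neuron number.

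In 25 of 144 sets of 8 replicates 1 library stood apart from the other 7 by the size of its gap to the nearest relative to the range (Dixon test at 95%). For independent sets of normally distributed values chance gives this in about 1 of 20 sets. Here the sets shared libraries, the added tissue lists were chosen after the libraries were examined, and the genes near Htt were taken from those called. The 25 sets therefore cannot be held against that rate. Total counts were 40.2 M in Q20 6-month M4 (others 36 to 37.9 M). Tissue levels are mean log2 CPM. Thalamus genes stood at 4.39 in Q140 10-month F2 (others 1.38 to 2.49) and 3.81 in Q50 6-month M4 (1.08 to 2.06). Liver genes stood at 7.16 in Q50 10-month M4 (others -3.06 to -0.74), 1.64 in Q50-cohort wild-type 6-month F3 (-3.01 to -2.47), -0.27 in Q92 10-month M4 (-2.77 to -2.28), -1.04 in Q92 6-month M4 (-2.87 to -2.1) and -1.9 in Q20-cohort wild-type 10-month M3 (-2.86 to -2.49). Midbrain dopamine neuron genes stood at 2.8 in Q20 10-month F4 (others -0.53 to 0.69), 1.01 in Q20 6-month F1 (-0.5 to -0.03), 0.37 in Q50 10-month M4 (-0.26 to 0.03) and 0.36 in Q92 10-month F1 (-0.4 to -0.11). Pituitary genes stood at 4.79 in Q20 10-month F2 (others -3.23 to -0.02), 3.47 in Q50-cohort wild-type 6-month F2 (-3.14 to -1.68) and -1.62 in Q92 6-month F1 (-3.29 to -2.63). Cortical projection neuron genes stood at 4.36 in Q50 6-month M3 (others 0.59 to 2.08), and choroid plexus genes at 2.51 in Q92 10-month F1 (0.33 to 0.73) and 1.26 in Q140 6-month M3 (-0.04 to 0.48).

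Genes near Htt also set single knock-in libraries apart. Abhd1 stood at 1.08 CPM in Q20 10-month M4 (others 4.54 to 5.81), 1.65 in Q50 6-month F3 (4.78 to 6.18), 3.39 in Q92 10-month F4 (4.67 to 5.65) and 7.12 in Q140 10-month M4 (4.66 to 5.82). Dpysl5 stood at 33.9 CPM in Q20 10-month M4 (others 44.2 to 51.2) and 36.6 in Q140 6-month M2 (46.8 to 52.5), and Atraid at 48 in Q140 10-month M4 (36.8 to 41.4).

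Effects that differed between ages by the test of the difference itself were found for 16 genes in Q50, 12 in Q92 and 215 in Q140 mice. Without Q50 10-month M4, the library with the highest liver level, the Q50 count was 0, and as many genes as the 16 came up in 48 of 100 splits of the libraries, highest other 254, so chance was not excluded. As many as in Q92 came up in 4 of 100 splits, highest other 16, and as many as in Q140 in 1 of 100, highest other 3. These splits exchanged ages within each group and sex. The age difference itself therefore added to their spread, which could lower their counts, so they cannot exclude chance for Q92 or Q140. The Q140 count was 8 with the library code as a covariate, 27 against the Q20-cohort wild types alone and 861 without the 5 libraries set aside for other tissue. An offset shared by all libraries of an age drops out of these 3 tests. A genotype effect that differs between sequencing sets cannot be told apart from one that differs with age.

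Shared striatal projection neuron genes were lower in Q140 mice at 10 months (median log2 fold change -0.49, 15 of 29 past the threshold). The library code was argued against by a median of -0.62 with that covariate, and thalamic tissue by a median of -0.63 with the thalamus level as a covariate, under which 26 of 29 fell. Fewer such neurons in the samples, with expression per cell unchanged, would raise the genes of every other cell type. The astrocyte median was -0.14, the vessel median -0.16 and the oligodendrocyte median -0.046, while the microglia median was 0.058 ± 0.0306 (bootstrap SE over genes). The bound written beforehand, an interquartile range of the neuron genes over 0.3, was met at 0.343, which by that rule alone argued against fewer neurons. It was not clearly beyond its spread, and the question was left open all the same, a choice made after the values were seen. The other part of the rule, on glial and vessel medians, was chosen after the result was seen. It asked for medians on both sides of 0 by a set multiple of their standard errors and was not met. Between the wild-type cohorts the astrocyte median was already -0.095 and the vessel median 0.004, and expression per glial or vessel cell was not measured. These medians therefore cannot decide on neuron number, which stayed open. A cohort difference stayed open. The median between the wild-type cohorts was 0.045, under the bound set by the Q140 median beforehand. This balanced -0.13 in females, within that bound, and 0.25 in males, past it in size and higher in the Q50 cohort. The Q140 median was -0.53 in females and -0.42 in males, but Q140 mice had no wild types of their own cohort. Cortical tissue stayed open too, with a cortical median of 0.16 and 0 of 10 genes past the threshold, and so did lower expression per neuron, which was not tested.

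Q92 mice had 943 genes past the threshold at 6 months and 73 at 10 months. Thalamic tissue went with this: 48 genes passed at 6 months with the thalamus level as a covariate, and over the 943 genes the median size of the log2 fold change went from 0.21 to 0.13 with median standard errors of 0.0554 and 0.0535, so calls ended because the changes shrank; 940 kept their direction and 43 their call. The choice of wild types went with it too, with 17 genes against the Q20 cohort, whose thalamus level was nearer to that of Q92, and 1870 against the Q50 cohort. A change of the Q92 effect with age was first read as excluded and then, after the values were seen, as undecided: 12 genes passed that test, but the simulated test by age called 46% of the smallest changes tried in the Q140 comparison, so few calls do not exclude small ones. Penk, Arpp21 and Krt9 kept their calls with the thalamus covariate, at log2 fold changes of -0.31, -0.21 and -0.46, and Ppp1r1b, at -0.14, did not.

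Genes called in Q20 or Q50 mice lay near Htt in 9 of 14 cases (64.3%), against 1.52% of the genes tested, and all 9 were also called in Q92 or Q140 mice. A chromosome 5 segment that differs from the wild types and was carried along with the knock-in allele is a candidate explanation. An effect that grows with CAG length was argued against for the 4 genes called in Q20 at both ages (Abhd1, Atraid, Dpysl5, Gm2420). Their Q20 change was a median of 109.7% of the Q140 change, and 76% at the lowest. Picking genes by their Q20 change by itself favours a large share. The calls at 6 months alone pick the same 4 genes, and in the other mice of 10 months their shares were 82.5%, 142.8%, 120.2% and 76%. Q20 and Q140 had unlike wild types as controls, and Gm2420 reached at most 0.62 CPM. Of the 4, Gm2420 (2.29 in Q20, 3.01 in Q140) and Atraid (-0.31 and -0.22, a shrinking change) were past the length trend at 10 months. For the 5 called in Q50 alone, growth past Q50 was argued against too, as the Q140 change was a median of 82.4% of the Q50 change and 106.3% at the highest (6030443J06Rik went from 1.27 in Q50 to -0.12 in Q140 at 6 months). These 5 were picked by their Q50 change, which by itself favours a small share. The calls at 6 months alone pick the same 5, and in the other mice of 10 months the highest share was 106.3% (Gm10471, at most 1.56 CPM). A step between Q20 and Q50 stayed open, and over all 9 genes 4 (44.4%) were past the length trend at either age. Segment ends that differ between mice stayed open: of 48 Q50, Q92 and Q140 libraries 5 lay within the wild-type range for at least 1 of 3 genes 8 to 9 Mb from Htt (Gm5067, Gm10471, 5031410I06Rik) and 5 (100%) for all 3, but 5 libraries are few and the genes lie close together. These were Q50 6-month F3, Q92 6-month F3, Q92 10-month F2 and M1 and Q140 6-month M2, and no sequence variants were read. Q50 6-month F3 lay within the wild-type range for all 9 genes, also those 2 to 4 Mb from Htt (Abhd1 1.65 CPM, Atraid 48.3 CPM), which a far segment end does not cover. Whether the Q50 label of this library is right was not tested. It was kept as Q50 in the main fits, and without it 13 genes passed for Q50 at 6 months (main 11).

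Other splits of the libraries into groups of the same sizes asked whether chance could give the counts, with 100 splits each and the real one included. Chance was called excluded where fewer than 5 of the 100 splits gave as many genes, with no correction over the comparisons. Chance was excluded at 6 months for Q140 (as many genes in 1 split, highest other 11, with 4113 in the fit used for the splits), Q92 (1, highest other 142), Q50 (4, highest other 541) and the CAG trend (1, highest other 351). It was excluded at 10 months for Q140 (1, highest other 55), Q92 (1, highest other 29), the wild-type cohorts (1, highest other 1) and the CAG trend (1, highest other 1), and for sex (2, highest other 724) and age (1, highest other 1) in wild types. It was not excluded for Q20 at 6 months (5, highest other 847) and 10 months (5, highest other 2576) or Q50 at 10 months (8, highest other 13). Nor was it for the wild-type cohorts at 6 months (100, highest other 68) or the Q140 effect by sex at 6 months (100, highest other 6) and 10 months (100, highest other 7), where the count was 0. Some splits gave several times the real count, as for Q20, Q50 at 6 months, the Q50 effect by age and sex, and what these splits share was not tested. They leave chance less clearly excluded for Q50 at 6 months and for sex.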

How the results depend on the processing

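Chosen only after the result was seen were the thalamus covariate, the thalamus and cortex covariates and the fit without the 5 libraries. Of 6034 values of named genes under alternatives, over 372 pairs of gene and comparison, 4816 kept direction and side of the threshold, 1173 were no longer past it, 6 were newly past it and 39 changed direction; of 298 counts 185 stayed within 1.5 times. RLE normalization left every split of rises and falls within 10 points. Where no reason is given, the cause was not tested.

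With females only, and so fewer libraries, counts were 2 (Q20), 0 (Q50), 520 (Q92), 1403 (Q140) and 1117 (trend) at 6 months, 2, 6, 40, 862, 13 (wild-type cohorts) and 454 (trend) at 10 months, and 0 for the Q50, Q92 and Q140 effects by age; Htt in Q92 at 10 months was 0.0018 (main -0.037). With males only they were 3 (Q50), 10 (Q92), 1518 (Q140) and 389 (trend) at 6 months, 0 (Q20), 0 (Q50), 0 (Q92), 1182 (Q140), 0 (wild-type cohorts) and 1535 (trend) at 10 months, and 0 for each effect by age; Htt was 0.081 and 0.0405 between the wild-type cohorts at 6 and 10 months and 0.0216 for the Q50 effect by age.

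Limma on FPKM changed values, normalization, filter and test together, so its moves have no single cause. With limma on log2(FPKM + 1) without a filter counts were 6 (Q50, 6 months), 491 (Q92, 6 months), 2 (Q20, 10 months), 34 (wild-type cohorts, 10 months), 0, 5 and 44 (Q50, Q92 and Q140 by age) and 31 (sex). With the filter they were 2 (Q20, 10 months), 0 (Q50 by age), 7 (Q92 by age) and 50 (Q140 by age); with log2(FPKM + 0.1), 0 (Q50 by age) and 55 (Q140 by age). Htt changed direction at small values: 0.0096, 0.0096 and 0.0101 between the wild-type cohorts at 6 months, -0.0111, -0.0111 and -0.0118 for the Q140 effect by sex at 6 months, and 0.0307, 0.0307 and 0.0319 for the Q50 effect by age. Splits with log2(FPKM + 1), log2(FPKM + 0.1) and no filter were 3344/1414, 3314/1430 and 3047/1281 rises/falls for Q140 at 6 months, 2381/1081, 2366/1095 and 2043/967 for the trend, 3069/984, 3009/1002 and 2774/846 for Q140 at 10 months, 2615/1357, 2609/1396 and 2379/1163 for the trend, and 26/29, 26/29 and 17/17 for the wild-type cohorts. Q20 at 10 months split 1/1 with log2(FPKM + 1) with and without the filter, and Q140 by age 29/15 without it. Cholesterol synthesis genes in Q140 at 10 months had a median of -0.026, and 0.013 with limma on log2(FPKM + 1).

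With the library code as a covariate counts were 7 (Q50, 6 months), 3 (wild-type cohorts, 6 months), 3267 (Q20, 10 months), 41 (Q92, 10 months), 27 (wild-type cohorts, 10 months), 0, 5 and 8 (Q50, Q92 and Q140 by age), 14 (sex) and 18 (age). Htt was -0.0101 (by sex, 6 months), -0.0113 (Q20, 10 months), 0.0249 (Q50 by age) and -0.0411 (age); Sst and Gpr17 by age were 0.0013 and 0.0964.

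With only the groups compared counts were 7 (Q50, 6 months), 1 (Q20, 10 months) and 147 (Q92, 10 months; 47/100 rises/falls, main 40/33); with no filter 570 (Q92, 6 months), 4 (Q20, 10 months), 79 (Q50 by age) and 48 (Q140 by age); with CPM of at least 1 in 8 libraries 7 (Q50, 10 months) and 1 (Q50 by age). With both wild-type groups as control they were 767 (Q20) and 55 (Q50) at 10 months. Against Q20 mice they were 19 (Q92) and 2339 (Q140) at 6 months, 295 (Q92) at 10 months, 137 (Q92 by age) and 1607 (Q140 by age), with Tcf7l2 in Q140 at 6 months at -0.0375 (main 0.96) and Htt by sex at -0.0414. Against the Q20-cohort wild types they were 17 (Q92) and 2398 (Q140) at 6 months, 25 (Q92 by age) and 27 (Q140 by age), with Htt by sex at -0.0759; against the Q50-cohort wild types 1870 (Q92, 6 months), 28 (Q92) and 2133 (Q140) at 10 months, and 7 (Q92 by age).

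With the thalamus covariate counts were 48 (Q92, 6 months), 4 (Q20), 129 (Q92), 96 (wild-type cohorts) and 2360 (trend) at 10 months, 8 (Q50 by age) and 43 (Q92 by age). Slc17a6 in Q92 at 6 months was -0.0093 (main 1.58), the 10-month trends of Abhd12b, Tnnt1, Prkcd, Rorb and Ppargc1a were 0.0209, 0.3592, 0.0294, 0.0023 and 0.0425, as the covariate takes up such genes, and Htt (Q50 by age) was 0.0067. With the thalamus and cortex covariates counts were 51 (Q92, 6 months), 4 (Q20), 182 (Q92), 119 (wild-type cohorts) and 1765 (trend) at 10 months, 6, 33 and 57 (Q50, Q92 and Q140 by age) and 779 (age). Tcf7l2 was -0.031, Htt by sex at 6 months -9e-04, Htt (Q50 by age) 0.0165, and the 10-month trends of Abhd12b, Tnnt1, Prkcd and Ppargc1a 0.2195, 0.3621, 0.1446 and 0.0471.

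With DESeq2 counts were 179 (wild-type cohorts, 6 months), 1 and 1 (by sex), 19 (Q20), 138 (Q92; 57/81 rises/falls, main 40/33) and 104 (wild-type cohorts) at 10 months, 1, 20 (16/4) and 421 (178/243) by age for Q50, Q92 and Q140, and 101 (sex). Without the 5 libraries they were 7 (wild-type cohorts, 6 months), 206 (Q92) and 138 (wild-type cohorts) at 10 months, and 0, 70 and 861 by age. With the replicate number as a block they were 6 (wild-type cohorts, 6 months), 0 (Q50 by age) and 140 (Q140 by age); libraries of equal number correlated by a mean of 0.034 and 0.005 at the 2 ages, so the numbers do not pair the libraries. Over Q20, Q50 and Q92 alone the trends gave 0 and 39 genes, with Htt, Msmo1 and Trib3 at 6 months at 0.024, 0.0024 and 0.0114; with log2 CAG length the 6-month trend gave 1775. Of list tests 81 passed with camera, 5 with an estimated correlation and 38 with fry.

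Without 1 library the lowest and highest counts at 6 months were 4 and 4 (Q20), 9 and 13 (Q50), 214 and 1209 (Q92), 3445 and 4212 (Q140), 0 and 114 (wild-type cohorts), 2443 and 3277 (trend) and 0 and 1 (by sex). At 10 months they were 3 and 11, 11 and 22, 41 and 87, 2623 and 3421, 24 and 64, 3500 and 4357, and 0 and 0. They were 0 and 25, 3 and 43 and 5 and 589 for Q50, Q92 and Q140 by age, 37 and 67 (sex) and 1210 and 2106 (age). Of 496 such counts 420 stayed within 1.5 times. The Q92 count by age was 3 without Q92 6-month F2, 4 without M1, 7 without F3, 43 without Q92 10-month F1, and 7 without Q92 10-month F2, Q20-cohort wild-type 6-month M2 or Q50-cohort 10-month M2. The Q50 count by age was 25 without Q50 10-month F1, F3, F4 or M1, 0 without M4, 7, 8 and 10 without Q50 6-month M1, M2 and M4, 0 without Q50-cohort wild-type 6-month F3, and 9, 8, 10 and 8 without 10-month M1, M2, M3 and M4. The Q140 count by age was 78, 6, 16, 359, 14 and 90 without Q140 6-month F1, F3, M1, M2, M3 and M4, and 6, 589, 433, 95, 69 and 5 without Q140 10-month F1, F2, F3, F4, M1 and M4. It was 447 and 49 without Q20-cohort wild-type 6-month M1 and M3, 443, 368, 120 and 42 without 10-month F4, M2, M3 and M4, 43 and 444 without Q50-cohort 6-month F3 and M1, and 470 and 27 without 10-month F2 and F4. In the simulated data 22% of the smallest differences by sex were called, so small ones would be missed.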

Other observations

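No hypothesis beyond those above was tested. Each of the 96 libraries was placed in a group by its labels. Over 144 pairs of replicates of a group and sex the spread of counts against that of resampled reads (chi-squared per degree of freedom) ran from 5.24 to 174 with a median of 15.2, so no pair was a copy of the same reads. The 50 genes with the most counts took 18.9% of counts at 6 months and 18.7% at 10 months.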
